A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

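Each of the 6 cultures, 3 of BY4741 wild type and 3 of the UPF3 deletion, came as 1 table with 7 libraries, and the labels call the cultures biological triplicates. Per the labels' protocols, total RNA was alkylated and made into libraries with the QuantSeq 3′ FWD kit, so reads come from the 3′ ends of transcripts. Per the file headers, the tables are SlamDunk output collapsed to one line per gene and library, and the submitters' processing notes name the genome build R64. The versions and settings of trimming, mapping, filtering and counting, and whether counting used strand, are not given in the sources used here. Per the file headers, the deposited counts are whole numbers of reads, reads with T>C and multi-mapping reads per gene window, and of T bases covered and converted. The conversion rate is a fraction, per the file headers, and was checked to equal converted over covered T bases. Other deposited columns (CPM as the authors scaled them, window length, T content and chase time) were used only for the window length and the times. Chase times are deposited without a unit and are read as minutes, so half-lives carry that assumption. Of 5560 gene identifiers, 5558 matched a locus tag of the reference table, which gave symbols and coordinates in build R64.

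Half-lives were computed per gene and culture. The conversion rate of the unlabelled library was subtracted from each labelled library, and a least-squares line of −log2 rate on chase time was fitted with the reads as weights. The half-life is the inverse of its slope. Genes needed a mean of at least 20 reads per labelled library, a signal above background at 3 or more chase points and a positive slope in all 6 cultures. This left 5471 genes by reads and 5333 by slope, with 138 left out for the slope, 107 of them in wild type and 50 in the deletion, some in both. Log2 half-lives were tested with limma 3.58.1 (lmFit, eBayes with trend and robust). Adjusted p values everywhere are by Benjamini-Hochberg, two-sided, with a threshold of 0.05. A nonlinear fit of a single exponential to the rates, also weighted by reads, left 5426 genes after 45 without a rate inside the range searched, and the line without the last chase point 5282.

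Read counts of the 6 labelled libraries were summed per culture and tested with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest), which kept 5555 genes. Standard errors of log2 changes are those implied by the quasi-likelihood F test. The test was first run with the robust option (299 higher, 9 lower) and then with the default, as the design fixed in advance names no option (310 and 10). Of the 320 default calls, 308 were shared. Normalised CPM are counts over TMM-scaled library sizes. DESeq2 1.42.0 was run as an alternative. Analyses used R 4.3.3 with the data.table package (1.17.8), and figures Python 3.11.15 with matplotlib 3.10.9.

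Gene lists were written before the data were examined: known NMD substrates, genes with upstream reading frames, frameshift genes, Ppr1 pyrimidine genes, NMD factors, decay machinery, inefficiently spliced genes, hosts of small nucleolar RNAs, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, glycolysis, respiration, stress response, amino acid synthesis, sulfur and methionine, iron and copper, phosphate, telomere and telomerase, a-cell mating, markers of the opposite mating type, meiosis and sporulation, histones, cell cycle and proteasome. Some genes are in more than one list. A list needed 3 measured genes. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. 2 more lists, genes with introns and pseudogenes, had 0 members in the reference table used here and were left out. Overlap of longer half-lives and more reads was tested with Fisher's exact test and Spearman's rho across genes. Culture medians were compared with exact permutation tests, two-sided, where 3 against 3 give 0.1 at the smallest, and first label also with sign flips over same-numbered pairs, where 3 pairs give 0.25.

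Named genes followed a rule fixed in advance. UPF3 came first. Each comparison then named the 10 largest rises and 10 largest falls by fold among called genes whose cultures did not overlap or, where none passed, the 5 lowest p values. CPA1, PPR1, ALR1, CTR2, EST1, EST3 and FLO8 were named whatever their values, as were 2 to 4 members of each described list with the lowest p. Genes called by the nonlinear fit or without the last point were named outside this rule, after their values were seen.

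The methods were tested on simulated data with 100 genes changed at each size, drawn from the real cultures. For read counts over 5555 genes, edgeR recovered 8% of changes of log2 size 1 and 87% of size 2 with 1 false call, and DESeq2 42% and 99% with 26 false calls. For half-lives over 5426 genes, the line recovered 65% and 95% with 12 false calls, the line without the last point 84% and 84% with 3, and the nonlinear fit 88% and 97% with 7. The simulated decay was a single exponential, so it holds no label that stays in RNA. Simulated half-lives were only lengthened, and all genes had the same scatter between cultures, the median of wild type. Recovery of genes with larger scatter may therefore be lower than these shares.

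Replicates were compared before averaging, by Pearson correlation of log2 read counts plus 1. Chi-square per degree of freedom between cultures of one genotype ran from 35.6 to 2831, so none of these cultures was a copy of another. Deviations of same-numbered cultures from their genotype means correlated across genes at 0.939, 0.910 and 0.866 in read counts, which pairs the numbers there. Replicates 2 and 3 also correlated across numbers (up to 0.823), and the pairing comes from the data, not from a label. Half-lives showed no such pairing. Libraries held 11045419 to 23761767 reads, 12477779 to 17032584 in the unlabelled ones, and reads carry no molecular identifiers in the tables, so counting error is only part of the error. Alternatives changed the background subtraction, the weights, the signal, the chase points used, the read minimum, the fit, the scaling, the gene filter, the block and the cultures used.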

Results

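The decay of messenger RNA was followed by SLAM-seq in Saccharomyces cerevisiae with and without UPF3, a gene for a core factor of nonsense-mediated mRNA decay (NMD), the pathway that removes transcripts whose translation stops early. In SLAM-seq, new RNA is labelled with 4-thiouracil (4TU), the label is chased, and T>C conversions in the sequenced reads mark molecules made before the chase. The series set out to find NMD targets from changes in half-life. BY4741, a haploid laboratory strain of mating type a, was compared with a UPF3 deletion, each as 3 cultures that the labels call biological replicates. Each culture gave 7 libraries of 3′ ends: 1 without label (DMSO) and 6 with 4TU, at mean chase times of 0, 1.11, 3.92, 7.85, 17.9 and 57.7. The time unit is not given in the sources used here and is read as minutes throughout. The 42 libraries held 11045419 to 23761767 reads over 5560 genes.

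T>C conversion was high at the start of the chase in both genotypes and fell over it. Of all T positions covered, 2.53% to 2.77% were converted at the first chase point and 0.164% to 0.204% at the last, against 0.0249% to 0.0357% in the 6 unlabelled libraries. After subtraction of the unlabelled rate, the median gene carried 2.70% ± 0.158 converted T (SD, n = 3) at the first point in wild type and 2.52% ± 0.132 (n = 3) in the deletion, a difference of −0.176 percentage points (exact permutation test, two-sided, p = 0.3, smallest possible p = 0.1). By the same subtraction, reads with T>C made up 38.9% ± 1.67 and 37.7% ± 1.45 in the median gene (exact permutation test, two-sided, p = 0.3). Both values were lower in the deletion in 3 of 3 pairs of same-numbered cultures (exact sign-flip test chosen after seeing the data, two-sided, p = 0.25, the smallest possible), so a small difference in first label is neither shown nor excluded.

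**Figure D1:**
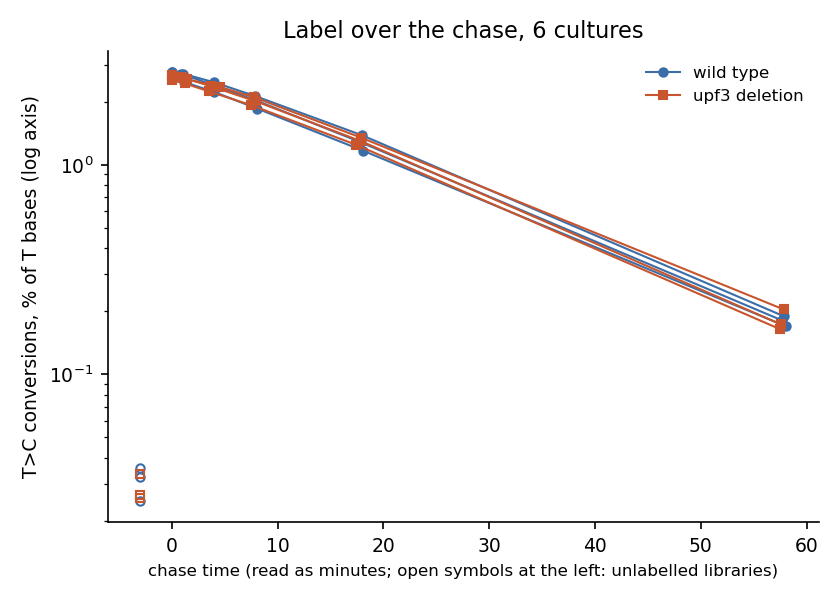
T>C conversions as % of T bases (log axis) against chase time (read as minutes) for each of the 3 wild-type and 3 deletion cultures, with one line per culture and open symbols at the left for the unlabelled libraries. The curves of both genotypes run from 2.53% to 2.77% down to 0.164% to 0.204%, and the unlabelled libraries lie between 0.0249% and 0.0357%.

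Replicate 1 of both genotypes stood apart from the other cultures in read counts. Log read counts per gene correlated at 0.998 between wild-type replicates 2 and 3 and at 0.991 between deletion replicates 2 and 3, but at 0.952 between wild-type replicates 1 and 2 and at 0.892 between deletion replicates 1 and 2. These correlations are across genes, which are not independent replicates. The library of deletion replicate 1 at chase time 4.57 also stood apart from its own culture, with a median correlation to the culture's other libraries of 0.909, the lowest of the 42, and 0.916% multi-mapping reads against 0.353% to 0.650% in the others. It held 204 reads of DAL7 against 759 to 2069 in the culture's other labelled libraries, and 70163 of TDH3 against 129134 to 171509. Without this library, an alternative chosen after seeing the data, edgeR called 340 genes changed in reads (320 with it, 315 shared), and limma 0 changed in half-life by the line and 20 by the nonlinear fit, the same numbers as with it. All 7 barcode identifiers of wild-type replicate 1 recurred in deletion replicate 3, and all 7 of deletion replicate 1 recurred in deletion replicate 2. Cultures that share barcodes cannot have been sequenced in one pool. Replicate 1 of both genotypes was therefore also set against replicates 2 and 3 as a possible pool.

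UPF3 (YGR072W, chromosome VII, 634304 to 635467, build R64) was lower in every deletion culture. It had 24.1, 27.5 and 30.7 normalised CPM in wild-type replicates 1 to 3, against 4.32, 5.40 and 6.18 in deletion replicates 1 to 3. The means were 27.4 ± 3.31 and 5.30 ± 0.934 (SD, n = 3), so the deletion kept 19.3% of the wild-type reads. The gene is 1164 bases long and its counting window 557 bases, and how much of that 3′ window lies outside the deletion is not known, so the remaining reads do not settle what was left of the gene.

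The first comparison asked which transcripts decayed at another rate without UPF3. With half-lives from a log-linear line, the lowest p values belonged to genes of unrelated function, and none passed the test. DIA3 (YDL024C, chromosome IV, 408451 to 409857), a gene of invasive growth, had half-lives of 9.91 ± 0.923 minutes in wild type and 22.4 ± 2.55 in the deletion (SD, n = 3). PET309 (YLR067C, XII, 267813 to 270710), a translational activator in mitochondria, had 5.69 ± 0.585 and 14.1 ± 0.904 minutes. SWP82 (YFL049W, VI, 36803 to 38674), a subunit of the SWI/SNF remodelling complex, had 8.68 ± 0.969 and 20 ± 3.83 minutes, and HPR1 (YDR138W, IV, 730578 to 732836), a subunit of the THO complex of mRNA export, 6.04 ± 0.253 and 14.8 ± 3.07. DCP1 (YOL149W, XV, 44938 to 45633), a subunit of the decapping enzyme, went the other way, from 22.3 ± 3.63 to 10.3 ± 0.502 minutes. Over both genotypes, DCP1 reads rose by 2.29 on the log2 scale from the unlabelled to the first labelled libraries. The rise was seen in 6 of 6 cultures (edgeR, adjusted p = 0.0157, a test chosen after seeing the data). Its level may therefore not have been steady, and its half-lives may not measure decay alone. All 5 had an adjusted p of 0.684 by limma. The sizes depended on the fit: log2 changes by the line were 1.17 in DIA3, 1.31 in PET309, 1.19 in SWP82, 1.27 in HPR1 and −1.11 in DCP1, and by the nonlinear fit 1.09, 0.61, 0.65, 0.32 and −1.52 (adjusted p from 0.144 to 0.512). Of 5333 genes tested, 0 had a longer and 0 a shorter half-life by limma. At an unadjusted p under 0.05 there were 213 longer and 89 shorter, where 267 are expected by chance in all. The 3 cultures of one genotype lay beyond all 3 of the other in 12% of genes, where chance gives 10%.

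With a nonlinear exponential fit, an alternative chosen before the data were examined, limma called 20 of 5426 genes longer and 0 shorter, and at an unadjusted p under 0.05 there were 804 longer and 31 shorter. DAL7 (YIR031C, IX, 413015 to 414679), a malate synthase of allantoin breakdown, went from 4.29 ± 0.890 to 16.6 ± 1.5 minutes (log2 change 1.97, SE 0.20, adjusted p = 0.0326). TEN1 (YLR010C, XII, 167320 to 167802), which caps telomeres, went from 5.61 ± 0.827 to 15.6 ± 1.82 minutes (1.48, SE 0.17, 0.0384). HTL1 (YCR020W-B, III, 155320 to 155556), of the RSC chromatin remodelling complex, went from 6.40 ± 0.0726 to 16.2 ± 0.488 minutes (1.34, SE 0.12, 0.0213). XRS2 (YDR369C, IV, 1215016 to 1217580), a DNA repair gene, went from 6.10 ± 0.484 to 21.9 ± 2.86 minutes (1.84, SE 0.14, 0.0213). The other called genes were YNR068C, RTC4, SLO1, YGL193C, ISC10, YMR320W, TCA17, THI22, WSS1, ATG5, PPT2, CTL1, MNT4, SPE1, HRT1 and CPP2, with log2 changes from 2.06 in YNR068C to 0.62 in CPP2. SLO1 and ISC10 are neighbours on chromosome V, as are ATG5 and PPT2 on chromosome XVI, so reads of one could have been counted for the other. In all 20 the deletion cultures lay above the wild-type cultures, as in 21.8% of all genes (23.0% in either direction), where chance gives 10% in either direction. The calls were lost by leaving out single cultures: limma then called 11 genes without wild-type replicate 1, of which 6 were among the 20, and 0 without any one of the other 5 cultures. The log2 changes moved less. They ran from 1.83 to 2.13 in DAL7, 1.38 to 1.59 in TEN1, 1.33 to 1.37 in HTL1 and 1.74 to 1.91 in XRS2. With the last chase point left out of the line, limma called 3 genes longer and 0 shorter (PET18, YDR215C and RTC4, named after their values were seen), and 538 longer and 32 shorter at an unadjusted p under 0.05.

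**Figure D2:**
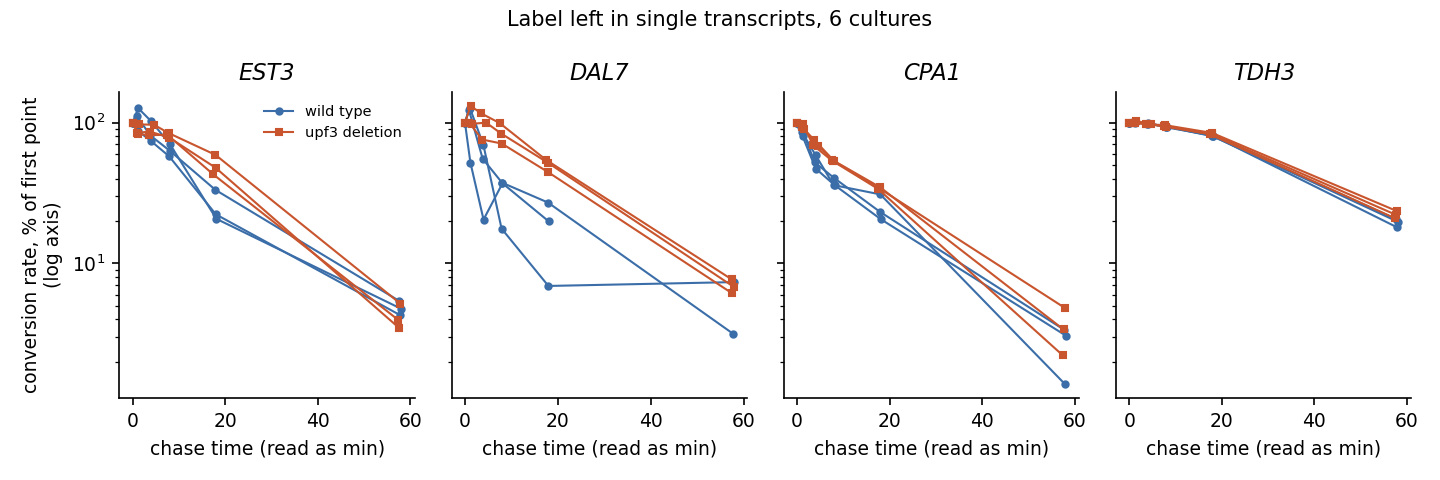
Conversion rate after background subtraction, as % of the first point on a log axis, against chase time (read as minutes) for EST3, DAL7, CPA1 and TDH3 in each of the 3 wild-type and 3 deletion cultures. Points at or below background are not drawn, and by the nonlinear fit DAL7 went from 4.29 to 16.6 minutes.

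The genes fixed in advance as NMD targets or close to them gave values that depended on the fit. EST3 (YIL009C-A, IX, 335666 to 336212), a telomerase subunit made by frameshifting, had a log2 half-life change of −0.03 by the line and 0.87 by the nonlinear fit (adjusted p = 0.985 and 0.0538 by limma). EST1 (YLR233C, XII, 607425 to 609524), another telomerase subunit, had 0.64 and 1.42 (0.872 and 0.0701). CPA1 (YOR303W, XV, 882899 to 884134), an arginine synthesis gene with an upstream reading frame, had 0.05 and 0.73 (0.983 and 0.0837), with 6.35 ± 0.267 and 10.5 ± 0.461 minutes (SD, n = 3) by the nonlinear fit. CPA1 reads rose early in the chase in every culture. They went from 2118 to 6437 by 8.08 minutes in wild-type replicate 2 and from 5970 to 13908 by 7.92 in deletion replicate 3. New unlabelled RNA lowers the conversion rate, so the CPA1 half-lives do not measure decay alone. PPR1 (YLR014C, XII, 172268 to 174982), an activator of pyrimidine genes, had 0.36 and 0.62 (0.932 and 0.298), and ALR1 (YOL130W, XV, 74400 to 76979), a magnesium transporter, 0.39 and 0.52 (0.872 and 0.365). CTR2 (YHR175W, VIII, 452872 to 453441), a copper transporter, had 0.31 and 0.06 (0.917 and 0.926), and the remaining UPF3 reads 0.75 and 1.29 (0.904 and 0.137). The line's value for UPF3 was set by 1 deletion culture, at 50.7 minutes against 14.8 and 10.1, and ran from 0.07 to 1.23 with one culture left out. None of these passed the test, and FLO8 was not analysed here.

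Over all genes the median half-life was 11.4 ± 0.153 minutes in wild type and 11.7 ± 0.399 in the deletion by the line (SD, n = 3; exact permutation test, two-sided, p = 0.5, smallest possible p = 0.1). Gene half-lives by the line ran from 6.52 to 18.5 minutes between the 5th and 95th percentiles in wild type. By the nonlinear fit the medians were 8.52 ± 0.501 and 10.3 ± 0.805 minutes, and by the line without the last point 8.62 ± 0.257 and 9.65 ± 0.517. In both of these, every deletion culture lay above every wild-type culture (exact permutation test, two-sided, p = 0.1, the smallest possible).

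Among the gene lists fixed in advance, none of 24 moved in half-life by the line (camera in limma, preset correlation, adjusted p from 0.171 to 0.822). An unadjusted p under 0.05 was reached by 3 lists: ribosome biogenesis (median log2 change −0.07), known NMD substrates (median 0.28) and telomere and telomerase genes (median 0.35). With fry, another test, also 0 lists passed. With the nonlinear fit, 5 lists lay higher than the other genes by camera with the preset correlation, and none of them with an estimated correlation (adjusted p = 0.285 for known NMD substrates, meiosis, telomere and NMD factors and 0.306 for phosphate). All 5 passed by fry (adjusted p from 0.00504 for telomere to 0.0105 for NMD factors). But fry tests a list against no change, not against the other genes, whose median was 0.16. It also passed lists that camera did not call, such as frameshift genes (0.00504). The known NMD substrates had a median log2 change of 0.56, with 2 of 19 members longer (DAL7 and TEN1), 17 not called and 6 longer when adjusted over the list alone (adjusted p of the list 6.3e-05). The list was drawn partly from earlier reports on such mutants. Of 15 meiosis and sporulation genes none was called, 8 were longer when adjusted over the list alone, and the median change was 1.03 (adjusted p = 7.6e-04). SPS4 had 2.05, MSH5 1.16 and IME2 1.27. The 14 phosphate genes had a median change of 0.46 (adjusted p = 0.00961, 0 called, 6 when adjusted over the list alone). The transporter gene PHO89 was highest at 1.84, and VTC3 had 0.56, below the list's upper quartile of 1.06. In the telomere and telomerase list, 1 of 9 was called (TEN1), 3 when adjusted over the list alone, with a median of 0.95 (adjusted p = 0.0103). This list shares EST1, EST2, EST3, STN1 and TEN1 with the known NMD substrates, so its result is not a separate one. The 5 NMD factors had a median of 0.72 (adjusted p = 0.0108, 0 called, 3 when adjusted over the list alone), with NMD4 at 0.99. UPF3 is a member although its reads in the deletion are remnants. Without it, an alternative chosen after seeing the data, the list had an adjusted p of 0.0424, and 0.323 with an estimated correlation.

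Against a median of 0.16 over all genes by the nonlinear fit, ribosomal protein genes (median 0.02, adjusted p = 0.00166), proteasome genes (0.02, 0.0103) and stress response genes (0.05, 0.0391) lay lower than the others by camera. Their medians and means were above 0 all the same, and no member was called in any of these 3 lists, over all genes or when adjusted over the list alone. With an estimated correlation these 3 did not pass (adjusted p = 0.614 for proteasome, 0.818 for stress response and 0.902 for ribosomal proteins). They did not pass by fry either (0.715, 0.513 and 0.293). By the line, the median, mean and test differed in sign for the lists of mitochondrial ribosomal proteins, cytosolic ribosomal proteins, stress response, respiration, amino acid synthesis, proteasome and frameshift genes.

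The second comparison asked which transcripts differed in abundance, from reads summed over the 6 labelled libraries of each culture. More transcripts rose than fell without UPF3. YGL262W (chromosome VII, 5312 to 5839) rose 45.5-fold, from 0.227 ± 0.00840 to 10.4 ± 0.948 normalised CPM (SD, n = 3; edgeR, log2 change 5.51, SE 0.21, adjusted p = 6.2e-04). YIR042C (IX, 435273 to 435983) rose 35.6-fold, from 1.69 ± 0.120 to 60.0 ± 11.5 (5.15, SE 0.23, 6.5e-04), and COS12 (YGL263W, VII, 2790 to 3932), a membrane protein gene near a chromosome end, 21.4-fold, from 1.71 ± 0.173 to 36.8 ± 16.2 (4.42, SE 0.37, 0.00264). DAL7 rose 8.58-fold, from 10.5 ± 2.18 to 89.9 ± 8.12 (3.10, SE 0.22, 0.00199). DAL5 (YJR152W, X, 719666 to 721297), the allantoate transporter, rose 7.28-fold, from 5.36 ± 0.748 to 39.1 ± 14.0 (2.86, SE 0.33, 0.00634). The rest of the 10 largest rises were YOL163W (XV, 9597 to 10106; 3.21), YHL012W (VIII, 78936 to 80417; 3.00), ULI1 (YFR026C, VI, 205748 to 206257; 3.00), YMR320W (XIII, 916746 to 917051; 2.92) and ABM1 (YJR108W, X, 628712 to 629083; 2.91), with adjusted p from 0.00134 to 0.0177.

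By edgeR without a block, 10 transcripts fell, and phosphate, iron and mating genes made up all of them but UPF3, while DESeq2 called 74 lower and edgeR with the replicate block 419. PHO84 (YML123C, XIII, 24037 to 25800), the high-affinity phosphate transporter, was 128-fold lower, at 688 ± 288 normalised CPM in wild type and 5.39 ± 2.24 in the deletion (SD, n = 3; edgeR, log2 change −7.00, SE 0.53, adjusted p = 0.00204). PHO84 overlaps the noncoding gene YNCM0001W and whether the counting used strand is not given in the sources used here, so reads of both are uncertain. SPL2 (YHR136C, VIII, 374654 to 375100), a regulator of phosphate uptake, fell from 65.3 ± 56.9 to 3.19 ± 2.0 (−4.36, SE 0.79, 0.0298), its wild-type mean being set by 131 in replicate 1. VTC3 (YPL019C, XVI, 514511 to 517018), of polyphosphate synthesis, fell by 1.58 on the log2 scale. Of the iron genes, FIT2 (YOR382W, XV, 1059531 to 1059992), a cell wall protein that holds siderophores, fell by 1.72, the mRNA-binding protein gene TIS11 (YLR136C, XII, 415801 to 416658) by 1.21, and the iron oxidase gene FET3 (YMR058W, XIII, 388822 to 390732) by 1.13. Of the mating genes, FUS1 (YCL027W, III, 71803 to 73341) fell by 1.28, ASG7 (YJL170C, X, 101150 to 101779) by 1.00, and BAR1 (YIL015W, IX, 322342 to 324105), the protease that degrades alpha factor, by 0.84. UPF3 itself fell by 2.37 (SE 0.21, adjusted p = 0.00297). The adjusted p of the other 7 falls ran from 0.0136 to 0.0456.

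**Figure D3:**
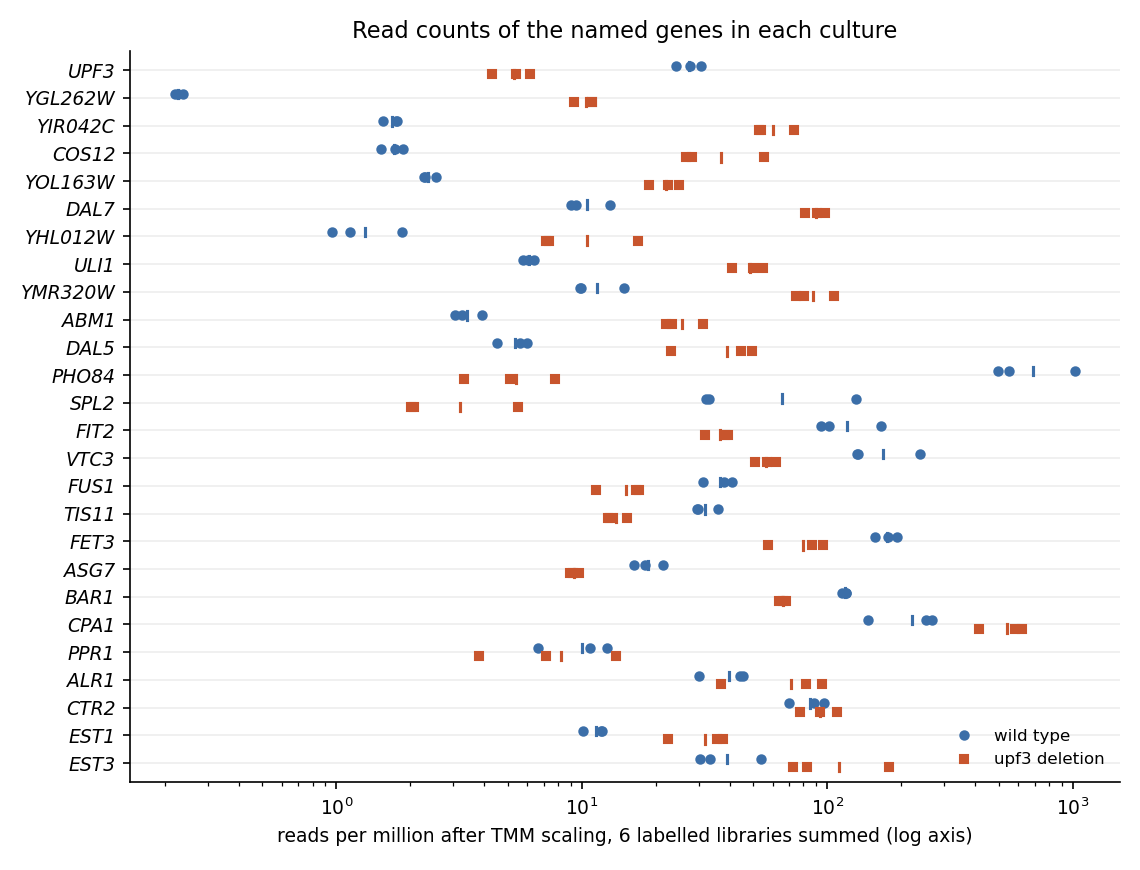
Normalised CPM (log axis) of 26 named genes in each culture, circles for the 3 wild-type and squares for the 3 deletion cultures, with ticks at the group means. PHO84 lies at 688 in wild type and 5.39 in the deletion on average, and YGL262W at 0.227 and 10.4.

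Among the fixed genes, EST1 rose 2.79-fold, from 11.4 ± 1.11 to 31.8 ± 8.17 normalised CPM (SD, n = 3; edgeR, log2 change 1.48, SE 0.24, adjusted p = 0.0208). EST3 had a log2 change of 1.51 (SE 0.42, adjusted p = 0.120), CPA1 1.28 (SE 0.30, 0.0658) and ALR1 0.84 (SE 0.38, 0.379), and these 3 passed with the replicate number as a block (adjusted p = 1.8e-04, 1.2e-04 and 0.00923). With DESeq2, EST3 (adjusted p = 0.0242) and CPA1 (0.00113) passed and ALR1 did not (0.265). CTR2 had 0.13 (adjusted p = 0.980) and PPR1 −0.28 (0.988), neither of which passed with or without the block or with DESeq2.

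In all, edgeR called 310 transcripts higher and 10 lower of 5555 tested. Of the 310, 267 rose over 2-fold and 84 over 4-fold, and the median rise was 2.97-fold. With the replicate block the counts were 1108 higher and 419 lower, which included all 320, and with DESeq2 489 and 74, which also included all 320. Leaving out both first replicates gave 1527 calls, an alternative chosen after seeing the data. Leaving out one culture gave 199 calls without wild-type replicate 1, 51 without wild-type replicate 2, 50 without wild-type replicate 3, 474 without deletion replicate 1, 129 without deletion replicate 2 and 97 without deletion replicate 3, and the first chase point alone gave 71.

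Of 25 gene lists tested on read counts, 5 lay higher and 11 lower than the other genes by camera with a preset correlation. Meiosis and sporulation genes rose most clearly: 9 of 19 members rose, 0 fell and 10 were not called (10 rose when adjusted over the list alone), with a median log2 change of 1.57 (adjusted p of the list 7.8e-12, and 0.0341 with an estimated correlation). SPS4, a late sporulation gene, rose by 2.55, the meiotic kinase gene IME2 by 2.55, the meiotic cohesin gene REC8 by 2.84 and ZIP1, which joins paired chromosomes, by 2.32. Known NMD substrates rose with a median of 0.94: 6 of 19 rose, 13 were not called, and 10 rose when adjusted over the list alone, against 12 with the replicate block (adjusted p = 1.1e-07, and 0.0477 with an estimated correlation). They included DAL7, FRE2 at 2.78, EST2 at 1.82 and EST1. Telomere and telomerase genes had a median of 1.15, with EST2, EST1 and TEN1 (2.09) of 9 higher, 6 not called and 6 higher when adjusted over the list alone, against 6 higher and 2 lower with the block (adjusted p = 0.00335, but 0.136 with an estimated correlation). EST1, EST2, EST3, STN1 and TEN1 are also in the list of known NMD substrates, so the results of these lists are not independent. Inefficiently spliced genes had a median of 0.34, with 4 of 21 higher, 17 not called and 6 higher when adjusted over the list alone, against 9 higher and 1 lower with the block (adjusted p = 0.00291, but 0.134 with an estimated correlation). Of these 4, SPO22 (1.61), SPO1 (2.04) and HFM1 (1.89) are meiotic genes and RPL22B (1.81) encodes a ribosomal protein.

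Genes of a-cell mating fell: 3 of 16 fell (BAR1, ASG7 and FUS1), 0 rose, 13 were not called, and 7 fell when adjusted over the list alone, against 12 with the replicate block. Their median log2 change was −0.56 (camera, adjusted p = 1.1e-08, and 0.0343 with an estimated correlation), and AGA2 had −0.74 (adjusted p = 0.0567). Beside them, the 4 markers of the opposite mating type had a median of 0.85, none called and 2 higher when adjusted over the list alone, as with the block (adjusted p of the list 0.0275, but 0.199 with an estimated correlation). SAG1 had 1.70 and STE3 1.04, with adjusted p of 0.0635 and 0.115. Phosphate genes had a median of −1.09, with 3 of 14 lower (PHO84, VTC3 and SPL2), 10 not called, and 7 lower when adjusted over the list alone, against 10 with the block (adjusted p = 1.8e-06, but 0.181 with an estimated correlation). GIT1, a permease for glycerophosphoinositol, rose by 2.81 (1 higher also when adjusted over the list alone). The median of the phosphate list was −1.92 between the first replicates and −0.89 between replicates 2 and 3.

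**Figure D4:**
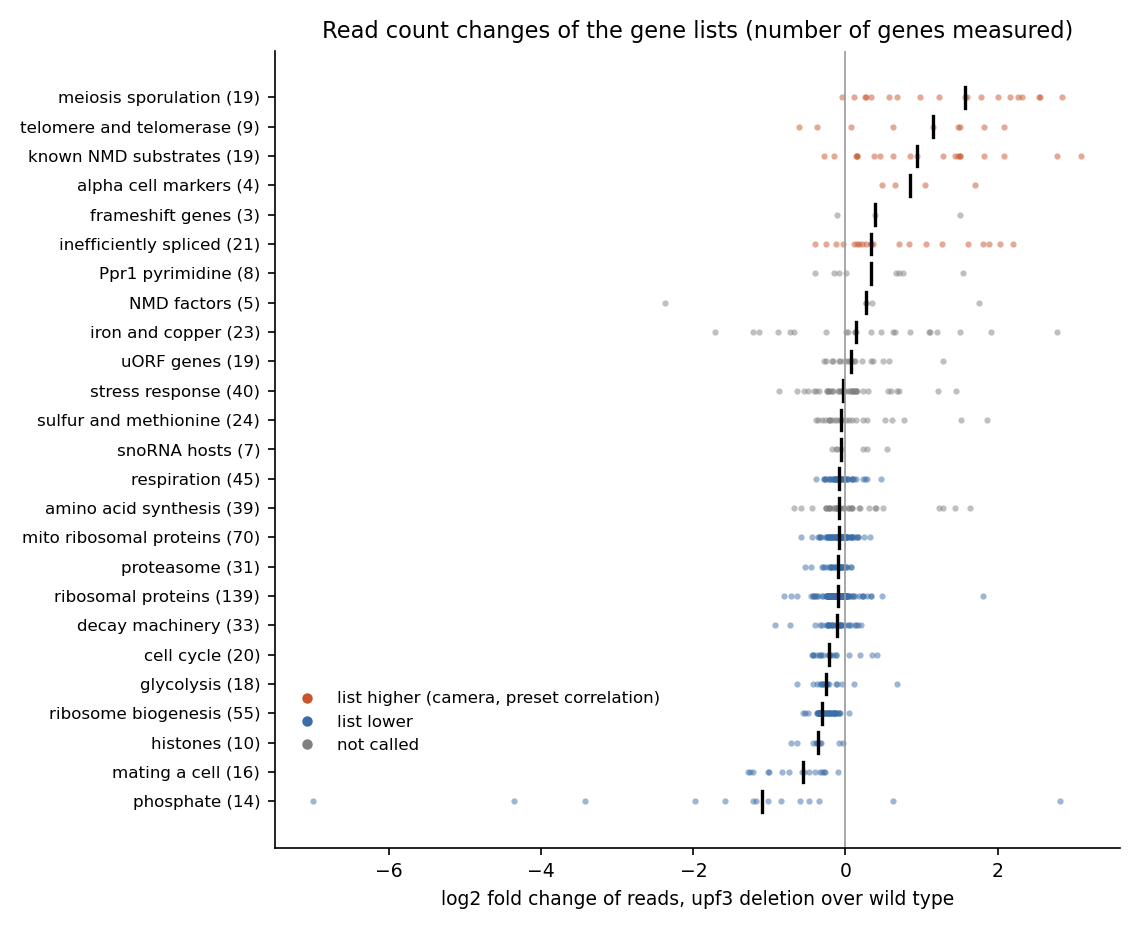
Log2 change in reads, deletion over wild type, of each member of the 25 gene lists, one point per gene and a black bar at each list's median, with red for lists higher, blue for lists lower and grey for lists not called by camera with a preset correlation. Medians ran from 1.57 for meiosis and sporulation to −1.09 for phosphate.

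Lists of growth and housekeeping genes were lower by small amounts, and almost none of their members was called. The 55 ribosome biogenesis genes had a median log2 change of −0.30 (camera, adjusted p = 1.8e-06, but 0.211 with an estimated correlation), the 139 ribosomal protein genes −0.10 (9.6e-04, but 0.799), the 70 mitochondrial ribosomal protein genes −0.08 (0.00390, but 0.554) and the 10 histone genes −0.36 (0.00536, but 0.472). The 33 genes of the decay machinery had −0.11 (0.00761, but 0.181), with DHH1 at −0.73 and DCP1 at −0.92. The 18 glycolysis genes had −0.26 (0.00790, but 0.282), the 20 cell cycle genes −0.21 (0.00827, but 0.199), the 31 proteasome genes −0.09 (0.0145, but 0.292) and the 45 respiration genes −0.08 (0.0478, but 0.292), the last of which did not pass with the replicate block (adjusted p = 0.0564). RPL22B was the only member of these 9 lists that rose, and none fell, while adjusted over the list alone no member was called. With the replicate block 21 ribosome biogenesis genes, 11 ribosomal protein genes, 7 histone genes, 6 mitochondrial ribosomal protein genes, 6 cell cycle genes, 4 of the decay machinery, 4 of glycolysis, 2 of the proteasome and 1 of respiration were lower, and 2 ribosomal protein genes and 1 gene each of glycolysis, cell cycle and respiration were higher.

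The remaining 9 lists were not called. Iron and copper genes went both ways: FRE3 rose by 1.92 and FRE2 by 2.78, both reductases, while TIS11, FIT2 and FET3 fell, and 18 of 23 were not called (camera, median log2 change 0.13, adjusted p = 0.651). Adjusted over the list alone 7 rose and 5 fell, against 10 and 6 with the replicate block. Of the 5 NMD factors, NMD4 rose by 1.75 and UPF3 fell, as also when adjusted over the list alone, and 3 were not called (median 0.28, mean 0.05, tested as lower, adjusted p = 0.990; without UPF3 tested as higher, 0.0930). Of 24 sulfur and methionine genes, MET1 rose by 1.85 and the sulfate permease gene SUL1 by 1.52, 3 rose when adjusted over the list alone, and 5 with the block, which called 1 lower (median −0.06, mean 0.15, tested as lower, adjusted p = 0.955). Of 39 amino acid synthesis genes, ARG8 rose by 1.22 and SNO1 by 1.64, and 2 rose when adjusted over the list alone, against 6 higher and 2 lower with the block (median −0.08, mean 0.08, tested as lower, 0.651). Among 8 pyrimidine genes of the Ppr1 regulon none was called, 1 rose when adjusted over the list alone (URA10, 1.54), and 4 were higher and 1 lower with the block (median 0.34, adjusted p = 0.357). The 40 stress response genes had a median of −0.03 and a mean of 0.03 (tested as lower, 0.428), with 0 called over all genes or over the list alone and 6 higher and 5 lower with the block. The 3 frameshift genes had 0.39 (0.428), with 0 called, 1 higher when adjusted over the list alone and 2 with the block. The 19 genes with upstream reading frames had 0.07 (0.998), with 0 called over all genes or over the list alone and 3 higher with the block. The 7 hosts of small nucleolar RNAs had a median of −0.06 and a mean of 0.08 (tested as lower, 0.998), with 0 called over all genes or over the list alone and 1 higher with the block.

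The third comparison asked whether transcripts that decayed more slowly were also more abundant. By the nonlinear fit, 14 of the 20 transcripts with longer half-lives also rose in reads, where 1.06 are expected by chance (Fisher's exact test, two-sided, p = 3.0e-14, odds ratio 43.6, 5426 genes). ISC10 rose by 2.68 and MNT4 by 2.18 in log2 reads, while XRS2 (0.30, adjusted p = 0.592 by edgeR) and SPE1 (0.32, 0.537) were not called in reads. By this fit, the transcripts that rose in reads had a median log2 half-life change of 0.79, or 1.73-fold, against 0.15 in the others, and 95.1% of them had a longer half-life in the deletion, against 75% of the others. By the line the change was much smaller, at 0.15, or 1.11-fold, against 0.03 in the others, with 64.2% against 54.1% longer. By the nonlinear fit, the median half-life of the transcripts that rose was 7.78 ± 0.286 minutes in wild type and 14.0 ± 0.842 in the deletion (SD, n = 3, 288 genes; exact permutation test, two-sided, p = 0.1, the smallest possible). These genes were chosen by the reads of the same cultures. The permutation does not repeat that choice, so its p is only descriptive. Across genes, changes in reads and half-life correlated with a Spearman rho of 0.430 by the nonlinear fit and 0.181 by the line, where no gene was called longer and Fisher's test could not be run. With the nonlinear fit, and reads and half-lives taken from different cultures, an alternative chosen after seeing the data, rho fell from 0.430 to 0.336, 0.347 and 0.345. Genes are not independent replicates, and both measures come from the same libraries.

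**Figure D5:**
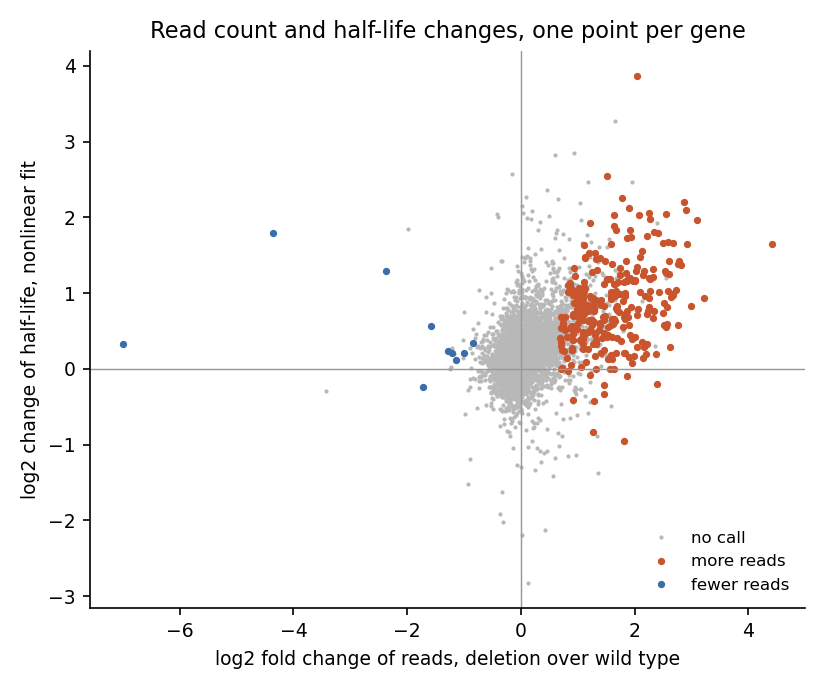
Log2 change in reads against log2 change in half-life by the nonlinear fit, deletion over wild type, one point per gene for 5426 genes, with transcripts called higher (288) and lower (10) in reads coloured. The transcripts called higher in reads lie mostly at longer half-lives, with a median of 0.79 against 0.15 for the others.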

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

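Of the tests in this part, those of the changes in reads during the chase and against the unlabelled libraries and both tests of the phosphate genes were chosen after the result was seen.

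PHO11 and PHO12, acid phosphatase genes, changed differently over the chase in the 2 genotypes. They are paralogs, and 0.0636% and 0.0165% of their reads were multi-mapping, but how the mapping handled shared reads is not given. From the first to the fifth chase point, PHO11 reads rose by 2.18 ± 0.217 on the log2 scale in wild type (SD, n = 3) and by 0.125 ± 0.126 in the deletion, a difference of −2.06 (SE 0.21, edgeR interaction test, adjusted p = 0.00897). PHO12 had 2.12 ± 0.197 and 0.136 ± 0.0662, a difference of −1.99 (SE 0.19, adjusted p = 0.00897). Both differences held in 3 of 3 cultures of each genotype without overlap.

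Reads also differed between the unlabelled libraries, whose reads no main comparison used, and the first labelled libraries: edgeR called 326 of 5515 genes, 221 higher and 105 lower with label. None was called different between the genotypes in this respect by edgeR (0 called, 65 at an unadjusted p under 0.05, where 276 are expected by chance). With so few low p values the test was conservative, so 0 calls do not show that no gene differed.

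Phosphate genes were lower in the deletion, with PHO84 at −7.00 and a list median of −1.09 (camera, adjusted p = 1.8e-06, but 0.181 with an estimated correlation). Of 14 members 3 were called lower, and GIT1 rose by 2.81. The median log2 half-life change was 0.46 by the nonlinear fit (quartiles 0.29 and 1.06) and 0.13 by the line, so no shortening was measured over the list. Reads of the list rose from the first to the fifth chase point, however (median log2 change 0.72, 6 of 14 higher). New unlabelled reads lower the conversion rate, and PHO11 and PHO12 reads rose far more in wild type, so faster decay in the deletion is not excluded. The assumed sequencing pools, replicate 1 against replicates 2 and 3, hold both genotypes in equal number. A shift between these pools could therefore not make the difference by itself. The list median was −0.89 or lower within each pool (−1.92 between the first replicates), with 13 and 12 of 14 genes lower. Other pool layouts were not tested. Less transcription, from a different phosphate state of the cultures or as an effect of the deletion itself, may explain the lower phosphate genes and was not tested, and whether culture conditions differed cannot be seen in these tables.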

How the results depend on the processing

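The alternatives with both first replicates left out, the pool as a term, conversions as weights, the unlabelled libraries, the robust option, disjoint cultures, UPF3 left out, 1 library left out, leaving out single cultures in list, overlap, median and label tests, and everything beyond the plain gene count by the nonlinear fit were chosen after seeing the data. Where no value shows it, the cause of a change was not tested.

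The count of genes with changed half-life, 0 by the line, was 20 by the nonlinear fit, 3 without the last point, 8 with conversions as weights and no last point and 1 by the nonlinear fit centred per culture. It stayed 0 under the other settings and without any one culture. Against 20 calls by the nonlinear fit there were 0 with the replicate block, 1 centred, 0 with both first replicates left out (fewer samples), 18 with the pool term (12 shared) and 0 to 11 without one culture (at most 6 shared), while all 20 kept their sign in each. Same-numbered cultures deviated together by only 0.0567, 0.0302 and 0.0243 in half-life by the line, so the block is not a pairing there. Not every culture correlated best with its own number.

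Fixed genes changed sign in half-life. For CPA1, half-life change, 0.05 by the line, was −0.0150 without background subtraction, −0.14 with both first replicates left out and −0.0546 to 0.14 without one culture. PPR1, 0.36, was −0.0512 to 0.81 without one culture. For CTR2, half-life change, 0.31 by the line, was −0.0359 without background subtraction, −0.0658 without the last point, −0.18 with both first replicates left out, −0.00714 with conversions as weights and no last point, −0.21 centred by the nonlinear fit and −0.0351 to 0.57 without one culture. EST3, −0.03, was 0.87 by the nonlinear fit with or without the replicate block, 0.61 centred, 0.10 from the share of reads with T>C, 1.14 without the last point, 0.40 with conversions as weights, 1.14 with these and no last point, and −0.0702 to 0.0118 without one culture. In reads, PPR1 (−0.28) was −0.87 to 0.0617 without one culture and CTR2 (0.13) was −0.21 in the unlabelled libraries.

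The 320 genes with changed reads became 1527 with the replicate block, 563 with DESeq2, 71 from the first chase point (fewer reads), 1716 with the pool term, 1527 from other fits with both first replicates left out, 182 in the unlabelled libraries (156 shared) and 50 to 474 without one culture. RLE factors gave 244, the robust option 308, and the median of all genes moved from −0.01 to −0.08. Among the genes and lists followed through the settings, the replicate block gained CPA1, ALR1 and EST3 in reads and lost the respiration list.

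Gene lists called in half-life, 0 by the line, were 8 by the nonlinear fit, 8 with the replicate block there, 5 without the last point (none of them with an estimated correlation, adjusted p from 0.386 to 0.750) and 0 to 1 without one culture. The 8 by the nonlinear fit became 0 with an estimated correlation and 3 to 9 without one culture. Leaving UPF3 out of the genes kept the counts of 0, 8 and 16 lists. Lists called in reads, 16, were 3 with an estimated correlation, 7 by fry and 10 to 16 without one culture. The Spearman correlation of changes in reads and half-life, 0.181, was 0.430 by the nonlinear fit and 0.330 without the last point. Without the library of deletion replicate 1 at chase time 4.57 it was 0.435 by the nonlinear fit, and genes changed in reads numbered 340 (315 shared). That setting left 20 genes changed in half-life by the nonlinear fit, all of them shared, 0 by the line and as many lists as before. From disjoint cultures by the nonlinear fit the correlation fell from 0.430 to 0.336, 0.347 and 0.345. Median half-life and first label kept their direction throughout.

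Among other values with one culture left out, 302 kept their direction and stayed called or uncalled, 181 lost the call, 2 gained one and 7 reversed. Under the other settings 660 kept direction and status, 120 lost the call, 12 gained one and 15 reversed. The 302 and 660 include values that were not called to begin with, such as half-lives by the line, which had no call to lose.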

Other observations

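Of the tests in this part, those of label left at the last chase point, of a shift of all genes, of reads shared between paralogs, of the rise in reads against half-life, and those of reads between the unlabelled and labelled libraries and over the chase were chosen after the result was seen.

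At the first chase point, labelled libraries held more reads of ribosome biogenesis genes than unlabelled ones of the same cultures: 16 of 55 members rose and 0 fell, with a median log2 change of 0.55 (camera, adjusted p = 3.9e-22, but 0.186 with an estimated correlation). The kinase gene RCK1 rose by 3.30 and RNH70, a nuclease of RNA processing, by 2.66, in 6 of 6 cultures each. INO1, of inositol synthesis, fell by 2.02 and the amino acid permease gene GAP1 by 1.51, in 6 of 6 cultures each. Lists of iron and copper (median −0.45, 0 higher and 2 lower), sulfur and methionine (−0.37, 1 and 3), glycolysis (−0.35, 0 and 4), phosphate (−0.37, 0 and 2), stress response (−0.23, 0 and 7) and respiration (−0.15, 0 and 2) lay lower by camera, with adjusted p from 3.0e-05 to 0.00180. None of these passed with an estimated correlation (adjusted p from 0.186 to 0.599).

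Read levels moved during the chase in both genotypes, though a chase is meant to change only the label. From the first to the fifth point, edgeR called 664 genes higher and 617 lower of 5518, from the first to the last 340 and 363, and from the first to the second 34 and 11. HSP30, a stress-induced membrane protein gene, fell by 6.84 to the fifth point (−7.25 to the last), and the glucose transporter gene HXT6 fell too (−3.27 and −3.37), in 6 of 6 cultures each. Ribosome biogenesis genes were higher at the fifth point (29 of 55 rose, 0 fell, median 0.42), and 99 of 139 ribosomal protein genes rose to the last point with 0 lower (median 0.58), while 20 of 40 stress response genes fell to the fifth point and 3 rose (median −0.45). With an estimated correlation these lists gave adjusted p of 0.511, 0.314 and 0.466. The directions did not hold over the whole chase. From the first to the second point stress response genes had risen (3 rose, 0 fell, median 0.17). At the last point ribosome biogenesis genes were near their first level (1 rose, 0 fell, median 0.07). Genes of a-cell mating were higher at the last point by both tests (8 of 16 rose, 0 fell, median 0.44, adjusted p = 6.9e-08, and 0.0417 with an estimated correlation).

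The half-life calls appeared with the nonlinear fit (20) and not with the line (0). Label left at the last chase point may account for part of this: in 1463 genes with early half-lives under 8 minutes, 1.5% to 2.58% of the first label was left where the early slope predicts 0.234% to 0.583%, and the lowest ratio of the 6 cultures was 3.61. Sorting genes by the slope that gives the prediction inflates this ratio. With each culture's genes sorted by the other 5 cultures it was still 2.27 to 4.79. In genes with early half-lives of 20 to 40 minutes, sorted in the same way, the ratio was 0.274 to 0.346. Less label was left in those genes than predicted, which leftover label cannot produce. Of the 20 genes, 16 were not called changed in reads from the first to the fifth point and 4 were, against 1281 of all 5518 genes. That test took both genotypes together, and a gene not called may still have moved. Read levels that move during the chase are therefore not excluded as a cause. A shift of all genes cannot be told apart from changes in the 20: their median lies 1.25 above that of all genes, but centring each culture left 1 call, with a median of 1.41 before (SE 0.15) and 1.14 after (SE 0.15) and centred adjusted p from 0.0159 to 0.256.

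Genes within 20 kb of a chromosome end were frequent among transcripts with more reads: 46 of 310, from 129 such genes in 5553 (odds ratio 10.8, 95% interval 7.22 to 16.1, Fisher's exact test, two-sided, p = 3.4e-26). Fisher's test takes genes as independent, while neighbours such as COS12 and YGL262W both rose. Its p value and interval do not measure the spread between cultures. Without genes with over 1% multi-mapping reads the odds ratio was 10.9 (6.96 to 16.9). How the mapping handled reads shared between paralogs is not given, so this cut may miss them and does not exclude them as a cause. Over 5 bins of mean count the common odds ratio was 8.14 (5.42 to 12.2). The mean includes the deletion cultures, whose reads also define a rise, so low counts in wild type are not excluded as a cause. Longer half-lives stay open: the median log2 half-life change by the nonlinear fit was 0.72 in 38 called genes near chromosome ends and 0.80 in 250 others. Changed silencing near chromosome ends could also be involved and was not tested.

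If longer half-lives alone raised the reads of the called transcripts, both changes would be of one size. By the nonlinear fit the half-life change lay below the change in reads by a median log2 of −0.69 in 288 genes, but these were chosen for their reads, which inflates the change in reads. In 1222 genes called from replicates 2 and 3 and measured in the first replicates, the difference was −0.12 (quartiles −0.67 and 0.44), and 0 genes were called from either other set of 4 cultures. Lengthening may therefore account for part of the rise, or for all of it only if the shift of all genes is counted. With 1 pair of cultures these cannot be told apart.

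The 6 cultures make 10 splits of 3 against 3, too few for a share under 0.05. Genes changed in reads numbered 320 in the real split and 0 at most in the others, so 1 split reached that count. For half-lives by the nonlinear fit the numbers were 20 and 0 (1 split), and by the line 0 and 0 (10 splits). Gene lists changed in reads numbered 16 and at most 13 (1 split), and in half-life by the line 0 and at most 1 (10 splits). Of the 10 splits, 4 part all pairs of same-numbered cultures, the real one included, and the highest other counts, 13 and 1 lists, came from these.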
